A study of Arabidopsis thaliana with 3 samples.

How the data were processed

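Total RNA of gcn20 and wild-type Col7 seedlings was, per the labels' protocols, amplified and labelled with Cy5 (gcn20) and Cy3 (Col7) and hybridised on 3 two-colour Agilent arrays with 60-base probes. The scans were quantified with Agilent Feature Extraction 9.5.1, per the submitters' processing notes, and the file headers give version 9.5.1.1. The deposited scanner files hold spot intensity values for each channel (mean signal, local background and a processed signal) and a LogRatio on a log10 scale, red over green. The file headers give the background and dye-normalisation methods as codes. The deposited series table holds log2 ratio values for 30380 probes. It was set against the LogRatio of each array's own scanner file and differed by a median of less than 4e-07, with correlations from 0.99997 upwards, so that its scale (log2) and direction (gcn20 over Col7) are settled. The column medians were 0.0023, -0.00565 and -0.00723, and the only centring seen is that of the LogRatio itself.

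The mean signals were corrected for local background with normexp (offset 50) and normalised within each array by loess in limma 3.58.1 under R 4.3.3. Control spots and spots marked as non-uniform or population outliers had weight 0, and 12, 20 and 12 outlier gene spots were left out on the arrays. Spots of a probe were averaged. Of 43803 gene spots, 34369 were given a locus by the RefSeq accession of the array design through the reference table (assembly TAIR10.1, used for names only), 329 by another accession and 1710 by a locus name in the file. The remaining 7395 spots have no locus here. Positions are those of the array files, whose headers name the January 2004 Arabidopsis build. Probes well above background in one channel on all 3 arrays were kept, which left 26727 probes. A gene stands by its brightest probe, and 19179 genes were tested. In 5809 genes with several probes, the probes' means differed by more than 1 on the log2 scale for 120 genes, and for 5 genes they lay on opposite sides of 0 by over 0.5. Saturated spots were kept. The brightest probe was saturated on all 3 arrays for 102 genes, of which 71 rose and 7 fell with the arrays scaled, and for these the ratio is at most a bound, or without meaning where both channels are saturated. In 344 genes Col7, and in 8 genes gcn20, was not well above background on any array. None of the genes named with a value belongs to these 344 and 8 genes, but for several of them one genotype was well above background on only 1 or 2 arrays.

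Each gene's mean log2 ratio was tested against 0 with limma (lmFit, eBayes) and Benjamini-Hochberg adjustment, with 3 arrays and no covariate. SEs are limma's moderated ones. Of 28 gene lists fixed before the data were examined, 27 had members on the array and the list of plastid-encoded transcripts had none with a locus. Members were matched by locus, and 12 of 652 entries whose symbol the reference does not carry were dropped. Members of both ribosomal protein lists were instead taken by the wording of the array's gene descriptions. Lists were tested with camera (preset correlation 0.01) with Benjamini-Hochberg adjustment over the lists, beside camera with an estimated correlation and fry. No list passed with an estimated correlation (smallest adjusted p = 0.759) or with fry (smallest adjusted p = 0.156). The rule for named genes, fixed at the same time, takes GCN20, GCN1 and GCN2, the 15 largest rises and 15 largest falls past the threshold with the same sign on all 3 arrays, and up to 4 members per list past the threshold or, where none passes, the 1 with the largest ratio. As no gene passed, the rule was applied to the fit with arrays scaled as well, after values had been seen. PSAL and PSAH2 are named outside it, also after values were seen.

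Alternatives fixed before the data were examined were the processed signals, no background subtraction, median centring, the LogRatio as deposited, scaling of the arrays to one spread, no filter and a filter on both channels, the mean over probes, a trended and robust prior, the series table, and leaving out each array. Added later were leaving out saturated probes, a threshold of 0.1, and alternatives to the scaled fit. The steps were tested on simulated arrays with 200 changed genes among 19179 for the comparison of gcn20 with Col7. Of 67 genes changed by 0.5 on the log2 scale, 64 were recovered, and all of 67 changed by 1 and all of 66 changed by 2, with 4 false calls. In a second simulation all genes varied and the ratios of array 1 were compressed. Of 1072 genes with a true log2 ratio of at least 1, 1045 were recovered without scaling and 1071 with it. Their median estimate was 0.85 without scaling and 0.73 with it, against 1.08 and 1.09 with equal arrays, so compression on array 1 lowers the estimates. The real data gave 0 genes without scaling, so this simulation does not reproduce their spread. The arrays carry no read depth. Their precision rests on signal over background and on the number of arrays.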

Results

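RNA of Arabidopsis thaliana seedlings carrying the gcn20 mutation was compared with RNA of wild-type Col7 seedlings on 3 two-colour microarrays. GCN20 (listed in the reference as ABCF3, locus AT1G64550) encodes an ATP-binding cassette protein related to the yeast Gcn20, a partner of Gcn1 and of the kinase Gcn2 that phosphorylates the translation initiation factor eIF2. On every array the mutant RNA carried Cy5 and the wild-type RNA Cy3, so 1 group of 3 replicate ratios, log2(gcn20/Col7), was obtained and the dyes were never exchanged. The labels give the age of the seedlings as 2 weeks in one field and a growth period of 20 days on MS plates in another. Nothing in the labels says whether the replicates came from separately grown plants, so the p-values measure only the spread between these arrays. Each array held 43803 gene spots, of which 67.3% to 71.0% were well above background in the mutant channel and 62.6% to 66.7% in the wild-type channel. The number of arrays limits the precision. A ratio was tested for 19179 genes.

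The GCN20 transcript was lower in the mutant on all 3 arrays. Its brighter probe, on chromosome 1 from 23973307 to 23973366 in the array's January 2004 build, gave log2 ratios of -1.66, -4.06 and -4.11, with a mean of -3.28 ± 1.40 (SD, n = 3). The mutant signal at this probe was 31.7% of the wild-type signal on array 1, 6.0% on array 2 and 5.78% on array 3. A second probe, from 23972919 to 23973071, gave -1.72, -4.33 and -4.33. The type and place of the mutation are not in the labels, so whether these probes lie in the changed part of the gene is unknown. Transcripts of the other GCN genes did not follow GCN20. GCN1 (listed as ILA, AT1G64790), which lies 91.9 kb away on chromosome 1, had log2 ratios of 1.65, 1.43 and 1.09 at its brighter probe and 0.85, 0.63 and 0.95 at the other. GCN2 (AT3G59410) had a mean log2 ratio of -0.06 ± 0.14 (SD, n = 3) and an adjusted p of 0.669, and its sign turned to 0.01 when the arrays were scaled.

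The ratios on array 1 were smaller than those on arrays 2 and 3, which affects every count that follows. The SD of the log2 ratios over genes was 0.24 on array 1, 0.76 on array 2 and 0.63 on array 3. Across genes, which are not independent replicates, Pearson's r was 0.84 between arrays 1 and 2, 0.87 between arrays 1 and 3 and 0.93 between arrays 2 and 3. The least-squares slope of array 1 on the mean of arrays 2 and 3 was 0.31. All 3 arrays had the same sign for 14757 genes, or 76.9% of those tested, and a dye bias that repeats on every array would add to this share.

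**Figure D1:**
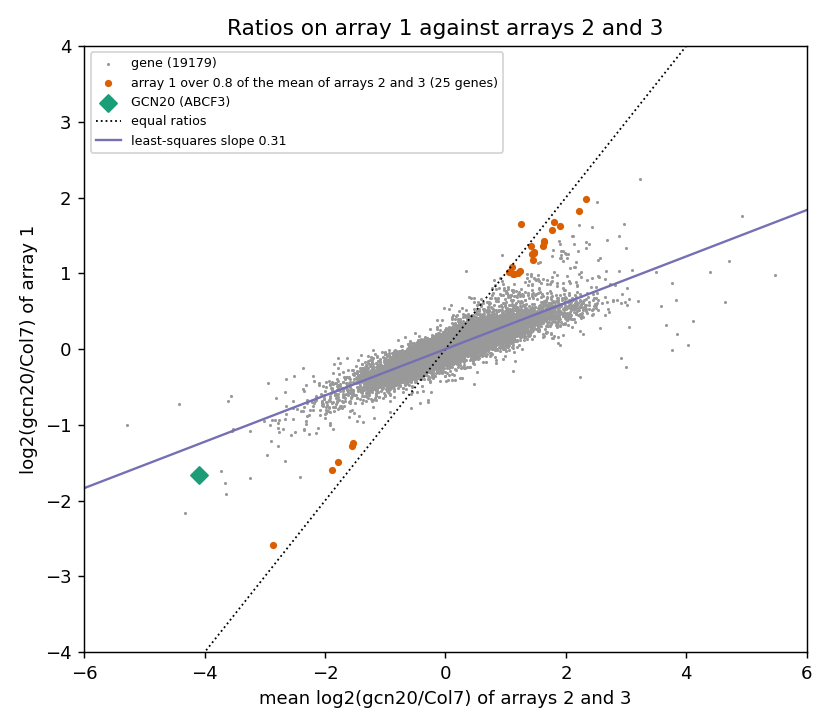
Each grey point is a gene, with the log2(gcn20/Col7) ratio of array 1 on the vertical axis and the mean of arrays 2 and 3 on the horizontal axis. Genes lie along a line of slope 0.31, GCN20 (green diamond) lies at -1.66 on array 1, and the 25 genes in orange kept over 0.8 of their ratio on array 1.

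With the ratios as they were, no gene passed the test set before the data were examined. The limma fit gave 0 genes higher and 0 genes lower in gcn20 at an adjusted p under 0.05, with a smallest adjusted p of 0.0705 that 4163 genes shared, while 8796 genes had an unadjusted p under 0.05. An adjusted p under 0.1 was reached by 4781 genes with higher and 3378 genes with lower ratios. With the arrays scaled to one spread, an alternative also set before the data were examined, 6298 genes rose and 4540 fell. Of these, 606 rose and 266 fell at least 2-fold in the scaled ratios, which are not the measured folds. As 10838 of all 19179 genes passed in this fit, many members of any list pass, and the counts per list below stand beside that share. Leaving out one array from the scaled fit gave 4567 to 6408 rises and 2914 to 4937 falls, so the number of falls is the less stable. Without array 1 and with no scaling, 5806 genes rose and 4378 fell, while leaving out array 2 or array 3 gave 0. In the paragraphs that follow, "rose" and "fell" refer to genes past an adjusted p of 0.05 with the arrays scaled. The log2 ratios and SEs are those of the unscaled fit over 3 arrays, in which the same genes did not pass. Each array was centred on its own genes, so a rise or fall is relative to the other genes, not an absolute amount. Scaling multiplied the ratios of array 1 by 2.16, those of array 2 by 0.63 and those of array 3 by 0.74. It thus treats the smaller ratios of array 1 as a matter of spread. This is an assumption, since the spiked-in controls described below were not compressed on array 1 (slope 1.01).

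The 15 genes with the largest rises had varied functions, and no test was made of what they share. The list of genes with the largest changes was drawn from the scaled fit after values had been seen, since no gene passed in the unscaled one. The AAA-type ATPase gene AT2G18193 rose by a log2 ratio of 3.87 ± 0.71 (SE, n = 3). AT2G21640 had a mean of 3.98 ± 1.00 and AT5G51440, which encodes a small heat shock protein of the mitochondrion, 3.52 ± 0.79. HSP70 (AT3G12580) had 2.68 ± 0.58. The zinc finger genes RHL41 (2.90 ± 0.24) and STZ (2.21 ± 0.12), the jasmonate repressor gene JAZ7 (2.53 ± 0.31), the ethylene response factor gene ERF13 (2.32 ± 0.15) and CYP94B3 (2.16 ± 0.32), which encodes a jasmonoyl-isoleucine hydroxylase, also rose. The others among the 15 largest rises were AT5G60250, AT3G05727, AT4G05380, ANAC087, AT4G29780 and AT1G17960 with mean log2 ratios of 2.08 and above. The wild-type signal was well above background on only 1 of 3 arrays for AT5G51440, AT5G60250, AT4G05380 and AT1G17960, and on 2 for AT2G18193 and CYP94B3, so the sizes of these ratios are uncertain.

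The 15 largest falls included GCN20 itself and several genes of pathogen responses, with no test of what the genes share. LURP1, named for its late rise in response to a downy mildew pathogen, fell with a mean log2 ratio of -3.07 ± 0.40 (SE, n = 3). The glucanase gene BG3 had -3.02 ± 0.53, PCC1 had -2.73 ± 0.35, the chitinase gene CHI (AT2G43570) -2.17 ± 0.42 and the phospholipase gene PLA2A -2.45 ± 0.46. AT3G22235 and AT3G22240, which neighbour PCC1 on chromosome 3, had -3.60 ± 0.49 and -3.03 ± 0.43. The lipid transfer protein gene LTP3 had -2.77 ± 0.69 and varied between the arrays, from -1.07 to -4.66. ASN1, a dark-induced asparagine synthetase gene, had -2.73 ± 0.57, and the NAC transcription factor gene NAC6, also known as ORE1 and a regulator of leaf senescence, -2.53 ± 0.49. AT3G55240, AT4G13575, MRD1 and AT5G03350 completed the 15 largest falls, with means from -3.86 to -2.27. The probes of AT3G22240 and PCC1 were saturated on 1 array.

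**Figure D2:**
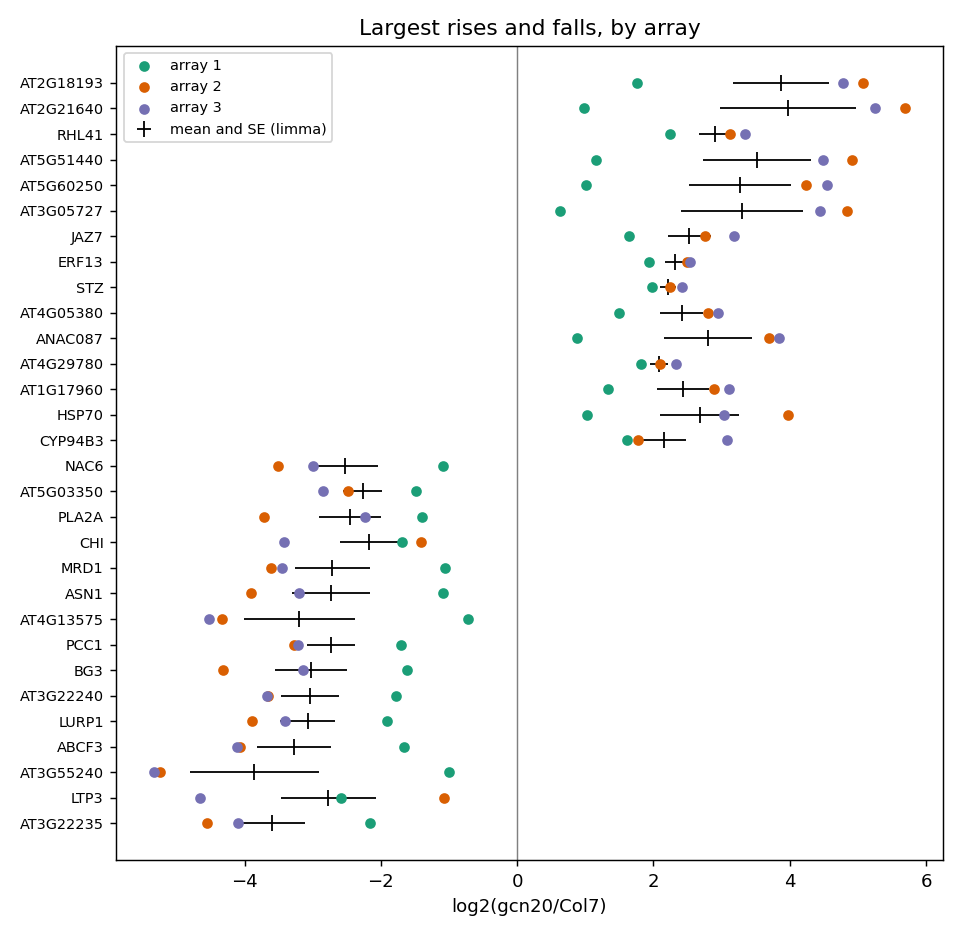
Log2(gcn20/Col7) on each array (coloured points) for the 15 genes with the largest rises and the 15 with the largest falls, with the mean and its moderated SE in black. Ratios of array 1 lie nearest 0 for most genes, for example 0.98 against 5.69 and 5.26 for AT2G21640.

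Cytosolic ribosomal protein genes rose together. Of 170 measured, 159 rose, 1 fell and 10 did not pass, and 162 were higher on all 3 arrays. The median log2 ratio of the list was 0.94, with medians of 0.31, 1.44 and 1.02 on the arrays. Members were taken by the array's descriptions, and their place in the cytosolic ribosome was not checked one by one. Among them, AT3G58660 had 1.61 ± 0.37 (SE, n = 3) and the RPS25 gene AT4G39200 1.47 ± 0.29, while AT5G39800 fell with -0.18 ± 0.09. Adjusted over the list alone, 156 passed in the unscaled fit, all of them higher. The set test (camera) gave the list an adjusted p of 1.71e-18, and an adjusted p = 0.759 with an estimated correlation. Of 19 genes for plastid ribosomal proteins, 13 rose and 1 fell, with a median of 0.46, an adjusted p of 0.00327 and an adjusted p = 0.759 with an estimated correlation. PSRP5 had 0.97 ± 0.20 and AT5G24490, the member that fell, -0.65 ± 0.14. When adjusted within the list, 2 were higher and 1 lower. Probes of 2 of these genes were saturated.

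Genes of cell division rose as well. Of 21 cell cycle and DNA replication genes, 16 rose and none fell, with a median log2 ratio of 0.64 (adjusted p = 0.00168 by camera, and adjusted p = 0.759 with an estimated correlation). The mitotic cyclin gene CYCB1;1 had 1.56 ± 0.35 (SE, n = 3) and TSO2, for a ribonucleotide reductase subunit, 0.87 ± 0.25. None passed when adjusted over the list alone. Of 17 flavonoid and anthocyanin genes, 14 rose and none fell, with a median of 0.65 (adjusted p = 0.00127, and adjusted p = 0.759 with an estimated correlation). They included the anthocyanin regulator gene PAP1 (AT1G56650; wild-type signal well above background on 2 arrays) with 1.11 ± 0.25, DFR, for dihydroflavonol reductase, with 1.24 ± 0.40, and GSTF12, for a transferase needed to store anthocyanins, with 1.34 ± 0.37. Within the list alone, 7 were higher.

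Jasmonate and salicylic acid genes moved in opposite directions on balance. Of 22 genes of jasmonate synthesis and response, 14 rose and 3 fell, with a median log2 ratio of 0.81. The regulator gene MYC2 had 2.03 ± 0.15 (SE, n = 3), while TAT3 and CORI3, both used as jasmonate markers, fell with -2.03 ± 0.32 and -1.59 ± 0.30. Adjusted over the list alone, 13 were higher and 3 lower. The set test gave an adjusted p of 0.0043, which became 0.0976 with the arrays scaled and adjusted p = 0.759 with an estimated correlation. Of 21 salicylic acid defence genes, 15 fell and 4 rose, with a median of -0.66 (adjusted p = 0.002, and adjusted p = 0.759 with an estimated correlation). BGL2, also known as PR2, had -2.28 ± 0.38, and SARD1, a regulator of salicylic acid synthesis, -1.57 ± 0.43, while GRX480 and WRKY46 rose with 1.14 ± 0.23 and 1.17 ± 0.20. Within the list alone, 14 were lower and 4 higher. Of 11 heat shock genes, 7 rose and 1 fell, with a median of 0.60. HSP70 (AT3G12580), one of the 15 largest rises, is not among the 11, because its symbol did not match. HSFA2, a heat shock factor gene, had 1.31 ± 0.29 and HSP90.1 1.25 ± 0.29, the first with a wild-type signal well above background on only 1 array, and BAG6 fell with -0.41 ± 0.13. Adjusted over the list alone, 8 were higher and 1 lower. Its adjusted p of 0.0422 became 0.0517 with the arrays scaled and adjusted p = 0.759 with an estimated correlation.

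Most of the measured genes of sugar starvation, senescence, autophagy and the abscisic acid response fell, and no member of these lists rose. Of 10 sugar starvation genes, 7 fell, with a median log2 ratio of -1.12 (adjusted p = 0.00141, and adjusted p = 0.759 with an estimated correlation). ASN1, SEN1 (-2.20 ± 0.45), BCAT-2 (-1.62 ± 0.32) and the galactosidase gene BGAL4 (-1.60 ± 0.37; SE, n = 3) were the largest. Of 9 senescence genes, 5 fell, with a median of -0.74 (adjusted p = 0.00582, and 0.759 with an estimated correlation), among them NAC6, SEN1, SAG13 (-1.79 ± 0.48; mutant signal well above background on 2 arrays) and NAP (-1.27 ± 0.22). SEN1 belongs to both lists. Of 13 autophagy genes, 8 fell, with a median of -0.38 (adjusted p = 0.00232, and 0.759 with an estimated correlation), led by ATG8F (-0.94 ± 0.16) and APG8A (-0.74 ± 0.14). Of 16 abscisic acid and drought genes, 9 fell, with a median of -0.29 (adjusted p = 0.00237, and 0.759 with an estimated correlation), among them RAB18 (-1.61 ± 0.34) and RD20 (-1.25 ± 0.30). Adjusted over the list alone, 7, 5, 7 and 0 genes were lower.

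**Figure D3:**
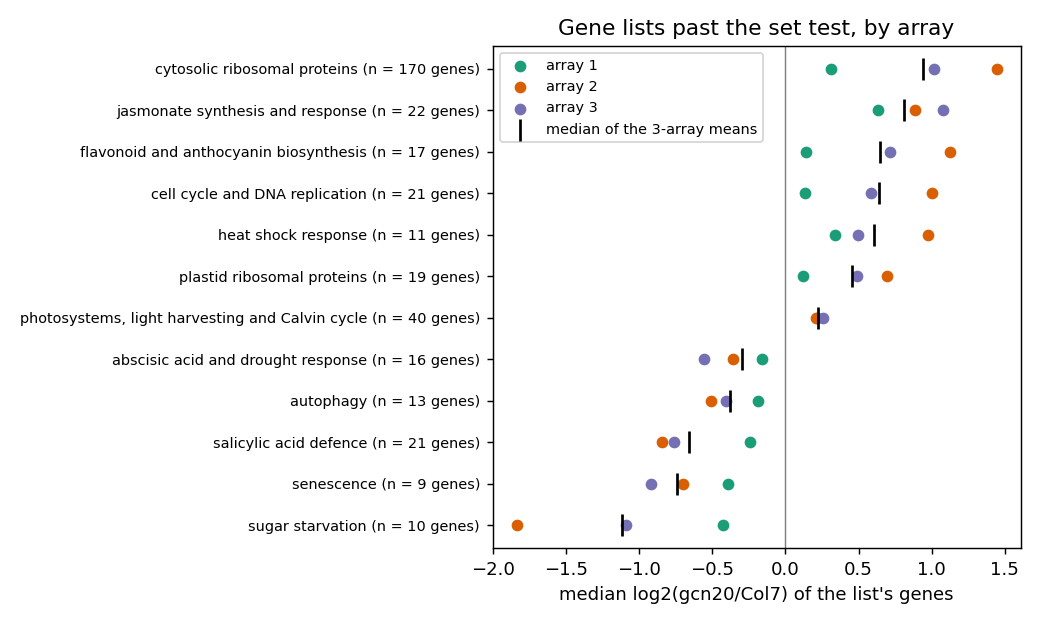
Median log2(gcn20/Col7) on each array (coloured points) and of the means over 3 arrays (black ticks) for the 12 lists past the set test with a preset correlation. The ratios of array 1 lie nearest 0 for 11 of the 12 lists, and the position of the photosystem list near 0.23 comes from saturated probes.

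Photosynthesis genes need a separate account, because 34 of the 40 measured had a brightest probe that was saturated on all 3 arrays, 26 of them in both channels. Where both channels are saturated the ratio carries no information on the direction, and where one is it is at most a bound. The list's median log2 ratio of 0.23 and its adjusted p of 0.00864 (adjusted p = 0.759 with an estimated correlation) are therefore not readings of expression. Of the 6 members whose brightest probe was not saturated on every array, 5 fell and none rose, with a median of -1.04. They included LHCB2.1 (-1.29 ± 0.36; SE, n = 3), PSAL (-1.09 ± 0.25), PETE1 (-1.05 ± 0.17) and PSAH2 (-1.03 ± 0.22). With probes saturated on all 3 arrays left out and the next brightest taken, a choice made after the values were seen, 29 genes could be measured. Probes saturated on fewer arrays were kept. Of these, 24 fell and 1 rose, and 23 were lower when adjusted over the list alone. The median was -0.80, and the list's direction turned to lower with an adjusted p of 3.58e-08, or adjusted p = 0.737 with an estimated correlation.

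The other 15 lists did not pass the set test. Their counts stand beside 6298 rises and 4540 falls among all 19179 genes. Counts of genes that rose and fell were 2 and 2 of 5 for the GCN pathway and ABCF family (which counts GCN20 among the falls and leaves out GCN1, EIF2A1 and EIF2A2, whose symbols did not match), 10 and 6 of 18 for pattern-triggered immunity, 4 and 6 of 16 for ethylene, 6 and 5 of 14 for cold response, 10 and 3 of 17 for the unfolded protein response, and 7 and 5 of 16 for oxidative stress. They were 10 and 7 of 27 for nitrogen and amino acid metabolism, 11 and 4 of 21 for glucosinolate synthesis, 4 and 3 of 14 for flowering time, 8 and 1 of 17 for the circadian clock, 2 and 2 of 10 for auxin response and 3 and 4 of 15 for chlorophyll synthesis, where 3 genes were saturated on all arrays and leaving out probes saturated on all arrays gave 1 and 5 of 13. The oxidative stress count leaves out AT2G21640, one of the 15 largest rises, whose symbol did not match. The adjusted p-values of the 15 lists by camera lay between 0.0677 for the circadian clock and 0.764 for cold response. Within these lists, ABCF1, a relative of GCN20, rose with 0.90 ± 0.23 (SE, n = 3), CSD2, for a copper/zinc superoxide dismutase, rose with 2.02 ± 0.37 and IMS2 of glucosinolate synthesis fell with -1.76 ± 0.33. The transcription factor gene WRKY40 and the ethylene synthesis gene ACS6 rose with 1.76 ± 0.18 and 1.91 ± 0.20, and the cold-related genes COR413IM1 and KIN1 fell with -2.23 ± 0.44 and -1.33 ± 0.24. Median and mean differed in sign for nitrogen metabolism (0.17 and -0.09), flowering time (-0.13 and 0.03) and stomatal markers (-0.10 and 0.08).

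Markers of other tissues gave no common direction. Of 11 root markers, 2 rose and 1 fell (adjusted p = 0.73), with PYK10, an abundant glucosidase gene of roots, at 1.26 ± 0.28 (SE, n = 3). Of 15 stomatal and guard cell markers, 6 rose and 6 fell (adjusted p = 0.56). Of 5 floral meristem and organ genes, 3 fell and none rose (adjusted p = 0.226), among them PI with -0.62 ± 0.13. Because the dyes were never exchanged, a probe's own dye bias cannot be told apart from a genotype effect. All 3 arrays belong to one slide, so slide could not be tested.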

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

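The tests of the smaller ratios on array 1 and of the second GCN1 probe were chosen after the result was seen. Those of the touch genes, of further probes and of the neighbours of GCN20 were written down before their values were looked at.

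Probes that could not be given a locus carried signal that no comparison used. Of 2564 such probes well above background, 465 were higher and 510 lower in gcn20 with the arrays scaled, and 0 passed in the unscaled limma fit. Of the probes placed on the plastid genome, 95 were well above background, with median log2 ratios of -0.05, -0.19 and 0.06 on the arrays. Of these, 36 were higher and 39 lower on all 3 arrays.

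The slope of array 1 on the mean of arrays 2 and 3 was 0.31 over genes. Weaker labelling, hybridisation or scanning is argued against by the 10 spiked-in control transcripts, whose log2 ratios on array 1 had a slope of 1.01 (SE 0.0095) against the other arrays. The ratios of the controls are LogRatio values, while the gene slope comes from the normexp and loess ratios. In the LogRatio, too, the SD over genes was smallest on array 1, at 0.40 against 1.03 and 0.86. Wild-type RNA in the mutant sample, at the 27.4% that GCN20 would need, predicts a median of 1.07 on array 1 for the 1656 genes at least 2-fold higher on arrays 2 and 3. The observed median was 0.39, and the median difference was -0.70. Mixing in both samples would need 48.4% mutant RNA in the wild-type sample and allows no ratio above 0.86, but 24 genes on array 1 passed that ceiling by more than 0.5, so it cannot be the whole cause, and the wild-type level of GCN20 on array 1 differed from the other arrays by -0.005 against a predicted -0.88. A smaller difference between the plants of this replicate stays open and was not tested. It would also have to account for the mutant's own GCN20 level, which was 9.78 (log2) on array 1 against 7.32 and 7.38. Wild-type RNA in the mutant sample together with a smaller difference was not tested either.

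On array 1, 25 of the 2445 genes with a mean log2 ratio beyond 1 on arrays 2 and 3 kept over 0.8 of it, among them STZ, WRKY40, CAF1a, ERF6, LOX3, JAZ1 and GCN1 (20 higher, 5 lower), named after their values were seen. Mechanical disturbance at harvest may contribute, but the 6 measured touch genes outside this group had a median log2 ratio of 0.40 on array 1, between the values set for and against it, with TCH3 at -0.44. Dye bias of single probes was not excluded either. For the 9 genes other than GCN1 with further probes these had a median of 0.60 against 1.28 for the first probes. A response of the mutant that is as large in this replicate as in the others stays open and was not tested.

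GCN1, one of the 25 genes above, was higher on all arrays at both probes. The second probe had 0.52 of the first one's ratio in the median (0.44 to 0.87), so the higher signal is not that of the first probe alone. Dye bias was not excluded, as the dyes were never exchanged and the cut-off was set after the values were seen. Of the 40 genes nearest to GCN20, 2 had an absolute log2 ratio of at least 1 (5%) against 6.58% of all other genes. The one-sided Fisher exact test gave p = 0.749. The 2 genes were AT1G64360 with a mean log2 ratio of -1.48 and AT1G64600 with 1.80. A block of sequence around GCN20 that changes many of its neighbours is thus argued against, but the test cannot exclude a change of few of them. The 40 genes do not reach GCN1 itself, so an effect of such a block on GCN1 was not tested. A change of GCN1 that follows from the loss of GCN20 stays open and was not tested.

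For 3 arrays there are 4 distinct sign patterns, too few for a share under 0.05. In the unscaled fit, the real pattern gave 0 genes, as did the others, so 4 of 4 gave as many. With the arrays scaled, 1 of 4 patterns, the real one, gave as many as 10838 genes, and the highest of the others gave 0.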

How the results depend on the processing

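The direction of 129 named genes was kept in 1661 of 1664 values under the alternatives set before the data were examined, the exceptions being GCN2 with median centring (0.0429) and with scaling (0.0115), and PSBW, whose brightest probe was saturated, with the mean over probes (-0.31). Most of these genes were named because they passed in the scaled fit, itself among the alternatives. The largest rises and falls were also required to have the same sign on all 3 arrays. Much of this agreement therefore follows from how the genes were chosen. The counts depended on how array 1 was treated. Saturated probes, the missing dye exchange and 3 arrays of one slide limit what the data can show, and genes not well above background in one genotype have only a bound. The causes of the changes that follow were not tested, except that fewer arrays or probes enter some of them. The scaled fit as leading value, its alternatives, the threshold of 0.1 and the removal of probes saturated on all 3 arrays were chosen after seeing the data. Array weights were tried too, but their estimate did not converge on 3 arrays and they have no value.

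Against 0 genes higher, 0 lower and 0 at least 2-fold either way, the processed signals gave 33 higher and 2 lower, no background subtraction 11 and 0, the LogRatio 56 and 5 and the values of the series 55 and 5, all of them at least 2-fold. Median centring gave 2119 and 739, of which 1115 and 322 at least 2-fold, and 74.1% of its calls were higher against 58.1% with scaling. Its median degrees of freedom were 38338, against 4.01 to 6.05 in the other fits, so its p-values rest on a variance pooled over genes. Scaling gave 6298 and 4540 (606 and 266 at least 2-fold in the scaled ratios). Leaving out one array gave from 0 to 5806 higher and 0 to 4378 lower, and 0 to 1656 and 0 to 787 at least 2-fold, the larger values without replicate 1. An adjusted p under 0.1 gave 4781 and 3378. The filters, the mean over probes and the trended prior left the counts at 0, with 8401 to 9857 genes at an unadjusted p under 0.05. Of the scaled calls, 5457 higher and 3996 lower were shared with the fit without replicate 1, and 0 were opposite. With the arrays scaled, the lower genes ranged from 2914 without replicate 3 to 4937 without replicate 1. GCN20 passed the threshold with median centring (-3.17, on the pooled variance) and scaling (-3.06), and ranged from -4.09 to -2.86 over the fits without one array, passing without replicate 1.

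All 12 list calls were lost with an estimated correlation (adjusted p = 0.759) and with fry (adjusted p of 0.156 for jasmonate and photosystems, 0.176 for heat shock and 0.215 for the others). The photosystem call was also lost with processed signals (0.234), scaling (0.0781) and the trended prior (0.206), ranged from 0.013 to 0.437 over the fits without one array, lost without replicates 1 and 3, and turned to lower with the mean over probes (0.0042) and with saturated probes left out (3.58e-08). Heat shock was lost with scaling (0.0517) and the filter on both channels (0.0981) and ranged from 0.0159 to 0.0523 over the fits without one array, lost without replicate 1. Jasmonate was lost with scaling (0.0976). The circadian clock list passed with no filter (0.0143), the series table (0.0498) and without replicate 2, in a range from 0.038 to 0.164, and the unfolded protein response with no filter (0.0384). Among lists not called on either side, the direction of the test turned for chlorophyll synthesis, nitrogen metabolism and root markers with median centring (0.76 each), nitrogen metabolism (0.887) and oxidative stress (0.53) with the mean over probes, oxidative stress with the filter on both channels (0.866), with saturated probes left out (0.871) and without replicate 2 (range 0.694 to 0.941), root markers with no filter (0.922), ethylene with the trended prior (0.694) and fry (0.404), and cold response with scaling (0.48) and without replicate 1 (range 0.659 to 0.721).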

Other observations

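The touch genes, of which PHI1 also belongs to the pattern-triggered immunity list, mostly had positive ratios over all 3 arrays. CML23, a calmodulin-like gene, had a mean log2 ratio of 0.78 ± 0.13 (SE, n = 3), PHI1 1.09 ± 0.28 and TCH4, for a cell wall enzyme, 0.69 ± 0.18. With the arrays scaled, 5 of 6 measured touch genes rose, and TCH3 fell with -0.57 ± 0.16.

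AT2G18193, AT2G21640 and AT5G51440 had the largest mean ratios without scaling among the 15 largest rises, and all 3 belong to the genes known to respond to disturbed mitochondria, which raised the hypothesis that this response may be active in gcn20. It was tested on 14 other genes of that response, listed before their values were looked at, except that AOX1A already belonged to the oxidative stress list. They were read on the same 3 arrays as the 3 genes that raised the idea, so the test is not independent. The median log2 ratio of the 14 was 1.22, above the 0.5 set beforehand, all 14 were higher on all 3 arrays, and all 14 rose with the arrays scaled. The medians on the arrays were 0.43, 1.49 and 1.48. NAC013, a transcription factor gene of the response, had 2.07 ± 0.48 (SE, n = 3), AOX1A, for the alternative oxidase, 1.36 ± 0.34, and CRF6 2.12 ± 0.37. The camera set test gave p = 6.39e-06 with the preset correlation and p = 0.292 with an estimated one, so the set test does not hold without the preset correlation. Whether mitochondria are disturbed in the mutant was not measured.

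The spiked-in control transcripts lay below their expected ratios by an offset that differed between arrays, at -0.70, -1.55 and -1.07 on the log2 scale. The slopes of observed on expected ratios were 0.886, 0.879 and 0.883. These controls were not used to set the level of the ratios. Measured against them, the LogRatio values of the genes would lie 1.62-, 2.93- and 2.09-fold higher on the arrays. A gene that fell relative to the other genes may therefore not be lower against the controls. The cause of the offsets was not tested.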
